A study of Mus musculus with 6 samples.

How the data were processed

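Spatial gene expression of mouse kidney was measured with 10x Genomics Visium, in which each barcoded spot on a slide captures RNA from the tissue above it. There were 6 libraries: 1 from a wild-type mouse (WT), 1 each from Alport syndrome mice (AS) at 2 months and at 5 months, 1 each from 5-month AS mice labelled as early treated and late treated with hEV, and 1 mixed library that held a wild-type and a heterozygous female together. The kidneys were frozen in embedding medium and cut as cryosections. The age of the WT mouse, the dose and dates of treatment, and the meaning of early and late were not given in the sources used here.

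The deposited matrices held counts of unique molecular identifiers (UMIs) per gene and spot, as whole numbers with no normalization. Per the file headers, the authors made the counts of WT and 5m AS with Space Ranger 1.2.1 and the counts of the other 4 libraries with Space Ranger 1.3.1. The submitters' processing notes name the mm10 genome build. The annotation version, the handling of strand and any filter on spots beyond the barcodes listed were not given in the sources used here. Each file listed 32285 genes, of which 40 symbols occurred more than once and were kept apart by identifier. Reads shared between close paralogs could not be told apart in these counts, which concerns Hspa1a and Hspa1b, the Serpina1 genes, the Cyp4a genes, Mettl7a2, C4b and the haemoglobin genes. Spot positions were not used here, so no map or distance was computed, and the 2 animals of the mixed library were kept as 1 sample.

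UMIs were summed over all spots of each library. Totals were 79699180 UMIs in WT, 91976637 in 2m AS, 52420718 in 5m AS, 48940875 in early treated 5m AS, 57325650 in late treated 5m AS and 74686937 in the mixed library. The sums were scaled to their effective library size (CPM) with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 0.858, 0.801, 1.13, 1.18, 1.17 and 0.934 in the same order. A floor of 3 counts corresponded to between 0.0407 and 0.0521 scaled CPM. With 1 library per group there was no replicate check of any difference and no test was run. The ratio of 2 libraries is given with a 95% exact (Clopper-Pearson) interval for a ratio of Poisson counts, and these intervals and floors cover counting error only, not differences between animals or sections. A gene was counted as apart when it had at least 20 scaled CPM in 1 of the 2 libraries and a ratio of at least 2-fold.

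In addition to Col4a5, which was reported in every library, genes were named by 1 rule. They had at least 20 scaled CPM in 1 of the 2 libraries and a difference of at least 1.5-fold in the same direction with plain CPM and with each spot weighted equally. Predicted genes, ribosomal protein, mitochondrially encoded, haemoglobin, immunoglobulin and sex-linked genes were left out. The 10 with the largest ratio in each direction were then taken, or 5 in each direction for early against late treated and for the mixed library. From each gene list the text describes, up to 4 members with the largest ratios were added. Not every gene chosen in this way is given in the text. The gene lists, this rule, the comparisons and the alternative settings were set before the data were examined.

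There were 42 gene lists, covering markers of kidney and immune cell types, programmes of injury, matrix, immunity, transport and metabolism, and genes that differ between the sexes. A member counted as measured with at least 5 scaled CPM in 1 of the 2 libraries. For each list with at least 3 measured members, the members at least 1.5-fold higher or lower were counted. The median log2 ratio was ranked among 10000 random lists of the same size matched on expression in 20 bins. A percentile below 2.5 or above 97.5 is called apart. The percentile compares a list with other genes of the same 2 libraries and does not measure differences between animals. The lists overlap in part, as with collagens in the fibroblast and the matrix lists, so they are not independent of each other.

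To follow the make-up of the sections, spots with at least 500 UMIs were clustered with scanpy 1.11.5 and leidenalg 0.10.2, using 2000 variable genes, 30 principal components, 15 neighbours, a resolution of 0.8 and seed 0. This gave 13 regions, each described by the genes that led it. Late-segment-led regions are those with late proximal tubule genes and no thick ascending limb genes among their leading genes. A region led by both, with Slc12a1, Umod and Slc22a7 among its leading genes, is not counted among them. A spot covers several cells, so a region is a kind of spot and not a cell type. Ratios were also computed within each region that had at least 20 spots in both libraries, and averaged over these regions with the pooled share of spots as weight (region-standardised), which leaves out spots of regions that the other library lacks. Shares of spots have exact (Clopper-Pearson) 95% intervals, which treat each spot as an independent draw. Spots of 1 library come from the same tissue, so these intervals do not cover differences between animals or sections. Genes were centred per library before clustering, so the region of a spot depends in part on what else its library held. The shares describe the make-up of each section under this clustering and are not results between groups. No doublet caller was used, since spots are not single cells.

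The procedure was tested on simulated data for 5m AS against WT with 5814 genes. It counted 100% of genes simulated at 3-fold, 0% of changed genes simulated below 2-fold and 0 unchanged genes, and its intervals covered the simulated ratio for 95.1% of genes. Of 100 lists without a simulated difference 2 were called apart, as were 20 of 20 lists with one. The simulated counts had Poisson error only, and genes varied independently of each other. The simulation therefore checks the computation. It does not show how often real lists of genes that vary together, or real sections of different make-up, would be called apart.

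The alternative settings were plain CPM, CPM without mitochondrially encoded genes, median-of-ratios factors from DESeq2 1.42.0, a minimum of 50 scaled CPM or no minimum, spots with at least 1000 UMIs, equal weight for each spot, libraries thinned to 48940875 UMIs, early-segment-led regions alone, region-standardised ratios at resolutions 0.8 and 0.4, and the mixed library in place of WT. Leaving out the late-segment-led regions was added after seeing the data. The region led by both thick ascending limb and late-segment genes stayed in. Its spots numbered 829 in WT, 496 in 2m AS and 208 in the mixed library. In 5m AS, early treated and late treated 5m AS they numbered 63, 107 and 122. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.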

Results

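The series profiled frozen kidney sections in Alport syndrome, an inherited disease of the type IV collagen of basement membranes, to follow its progression and the state after hEV treatment. There were 4093 spots in WT, 3212 in 2m AS, 1997 in 5m AS, 3549 in early treated 5m AS, 2892 in late treated 5m AS and 3352 in the mixed library. The median spot held 17790, 28433, 26054, 12736, 18187 and 21153 UMIs in the same order. Mitochondrially encoded genes took 11.9% of the UMIs in WT and at most 8.32% in the other 5 libraries. Levels below are scaled CPM, ratios carry 95% counting intervals in parentheses, and 1 library stood for each group. The counts of WT and 5m AS came from Space Ranger 1.2.1 and those of the other libraries from version 1.3.1, so in a comparison across versions the group and the version cannot be told apart.

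Col4a5 (ENSMUSG00000031274, protein coding, mm10 chromosome X, 141475385 to 141689234), the gene named in the Alport genotype, was lower in all 4 AS libraries than in WT. It stood at 11.9 in WT, 6.55 in 2m AS, 3.39 in 5m AS, 5.52 in early treated and 5.57 in late treated 5m AS, and 13.2 in the mixed library. The ratio to WT was 0.286 (0.244 to 0.334) in 5m AS and 0.552 (0.492 to 0.618) in 2m AS. Its partner chain Col4a3 had ratios of 0.896 in 5m AS and 1.47 in 2m AS, and Col4a4 had 0.587 and 0.827. The Y-linked gene Ddx3y was between 22.0 and 27.2 in the 5 libraries of single animals, with 0 counts in the mixed library, which allows up to 0.0430 scaled CPM. Xist, the RNA of the inactive X chromosome, was at 22.1 in the mixed library. By these genes the mixed library was female and the other 5 libraries were male, so sex also differs wherever the mixed library is compared.

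At 2 months, the Alport kidney had more RNA of fibroblast genes and of several single genes of the late proximal tubule than WT, and less RNA of intercalated cells, podocytes, renin and the unfolded protein response. Col3a1, a fibrillar collagen, was at 98.4 in 2m AS and 23.4 in WT, 4.20-fold (3.98 to 4.44). Ren1, which encodes renin, was at 42.4 and 169, a ratio of 0.250 (0.240 to 0.260). Cyp4a14, a fatty acid omega-hydroxylase, was 12.5-fold (11.2 to 14) higher. Of 6607 genes, 85 were at least 2-fold higher and 74 at least 2-fold lower.

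Fibroblast genes were higher, with 6 of 8 measured members past 1.5-fold and a median log2 ratio of 1.40 (percentile 100). Dcn, a matrix proteoglycan, was 3.51-fold higher. The matrix list had a median of 0.44 (percentile 100), with Fn1, which encodes fibronectin, 2.06-fold higher. Injury genes had a median of 0.58 (percentile 100), with 6 of 13 higher, among them Cryab at 2.59-fold, while Clu had a ratio of 0.501. Among complement genes 5 of 10 were higher, with C3 at 2.02-fold and Fgg, a fibrinogen chain, at 5.48-fold. The named genes also held Gc, the vitamin D binding protein, at 4.12-fold, and the late-segment genes Serpina1a at 12.1-fold, Serpina1d at 11.2-fold, Serpina1f at 7.79-fold, Mettl7a2 at 6.88-fold, Scd1, a fatty acid desaturase, at 5.20-fold and Cyp7b1 at 4.45-fold. Without late-segment-led regions the log2 ratio was 2.47 for Serpina1a, 1.98 for Serpina1f, 1.69 for Mettl7a2 and 0.83 for Cyp7b1, where it was 3.60, 2.96, 2.78 and 2.15. The late proximal tubule list as a whole, with a median of 0.26 and 4 of 10 higher, was not apart from random lists (percentile 84.4) and had -0.21 when region-standardised.

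Intercalated cell genes were lower, with 6 of 8 past 1.5-fold and a median of -1.13 (percentile 0). Slc26a4, the chloride-bicarbonate exchanger pendrin, had a ratio of 0.369 and Foxi1, a transcription factor of these cells, 0.350. The ammonium transporter Rhbg had a ratio of 0.267. Podocyte genes had a median of -0.63 with 7 of 13 lower, and endothelial genes -0.47 with 4 of 12 lower. The podocyte-led region held 5.60% (4.83 to 6.46) of spots in 2m AS and 8.45% (7.62 to 9.35) in WT. Region-standardised, the podocyte median was -0.505 (percentile 0.01), though some of these genes lead that region. Unfolded protein response genes had a median of -0.64 with 8 of 12 lower, including the chaperone Hspa5 at 0.465. Collecting duct principal cell genes had a median of -0.61, distal convoluted tubule genes -0.54, mitochondrially encoded genes -0.76 and glycolysis genes -0.27, all apart from random lists. The heat-shock genes Hspa1a, Hspa1b and Hsph1 had ratios of 0.110, 0.141 and 0.277, but the immediate early and heat-shock list, which does not hold Hsph1, had a higher median of 0.29 (percentile 99.5), with 6 of 13 higher and 4 lower. The other named lower genes were Cyp4a12a at 0.271, Hhatl at 0.275, Hsd17b11 at 0.281, Khsrp at 0.317 and Cyp2d12 at 0.324. Nuclear-encoded oxidative phosphorylation genes had a median of 0.27 and antigen presentation genes -0.09, neither apart from random lists.

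The 2 libraries came from different Space Ranger versions. Late-segment-led regions held 9.90% (8.89 to 11) of spots in 2m AS and 2.44% (1.99 to 2.96) in WT. A region led by both thick ascending limb and late-segment genes, not counted among them, held 496 spots in 2m AS and 829 in WT. The higher and lower counts were 54 and 96 with plain CPM, 41 and 151 without mitochondrially encoded genes and 116 and 66 with median-of-ratios factors. Against the mixed library the macrophage median was -0.59 where it was 0.35 against WT (0.18 and not apart when region-standardised), and the thick ascending limb median -0.55 where it was 0.56. The mitochondrially encoded median was 0.32 against the mixed library where it was -0.76, and the immediate early and heat-shock median -0.13 where it was 0.29. The mixed library itself, against WT, had medians of 0.53 for complement and 0.43 for injury genes, both apart, where 2m AS had 0.55 and 0.58. Its fibroblast median of 0.13 was not apart. In the mixed library 157 genes were at least 2-fold higher than in WT and 231 lower, more than in 2m AS.

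The 5-month Alport kidney differed from WT by high RNA of tubular injury, matrix, macrophage and complement genes and by low RNA of proximal and distal tubule transport genes. Havcr1 (kidney injury molecule 1, ENSMUSG00000040405, chromosome 11, 46735080 to 46779578) was at 152 in 5m AS and 0.395 in WT, 386-fold (265 to 586). Lcn2 (lipocalin 2, ENSMUSG00000026822, chromosome 2, 32384633 to 32388252) was at 129 and 0.512, 252-fold (181 to 362). Slco1a1, an organic anion transporter, was at 39.0 and 373, a ratio of 0.105 (0.1 to 0.109). Of 6795 genes, 330 were at least 2-fold higher and 283 at least 2-fold lower. Both libraries came from Space Ranger 1.2.1.

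Among 18 measured injury genes 15 were higher, with a median log2 ratio of 3.07 (percentile 100). Vcam1, an adhesion molecule, was 13.1-fold (12.1 to 14.2) higher and Cd44 10.5-fold. In the matrix list 20 of 22 were higher, with a median of 2.26 (percentile 100). Timp1, an inhibitor of matrix metalloproteinases, was 86.2-fold (67.8 to 111) higher, Tnc 16-fold and Col1a1 12.6-fold (11.8 to 13.4). All 10 fibroblast genes were higher, with a median of 3.41. The type IV collagen and basement membrane list had a median of 0.48 with 5 of 15 higher, as Col4a1 was 2.34-fold and Col4a2 2.17-fold higher.

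All 12 macrophage genes were higher, with a median of 2.65 (percentile 100), and Lyz2, which encodes lysozyme, was 23.1-fold (21.9 to 24.3) higher. Complement and acute phase genes had a median of 2.87 with 12 of 13 higher, and C3 was 32.2-fold (30 to 34.5) higher. Among NF-kB and chemokine genes 16 of 17 were higher, with a median of 2.01, and the monocyte chemokines Ccl2 and Ccl8 were 66.7-fold and 56.0-fold higher. Class II genes led the antigen presentation list, in which 11 of 16 were higher and Cd74 was 4.74-fold higher. The B and plasma cell list, with 3 measured members, had a median of 3.98, and Ighm was 24.9-fold higher. Interferon response genes had a median of 0.58 with 8 of 17 higher. Cell cycle genes had a median of 1.87 with 11 of 14 higher, and apolipoprotein and lipid handling genes 0.84, with Apoe 6.34-fold higher. The remaining named higher genes were Serpina10 at 473-fold (202 to 1460), Bcat1, an enzyme of branched-chain amino acid breakdown, at 203-fold (log2 ratio 7.67, and 6.30 when region-standardised), Ltbp2 at 140-fold and Aoc1, an amine oxidase, at 54.3-fold.

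Early proximal tubule genes were lower for 12 of 12 members, with a median of -1.20 (percentile 0). Slc6a19, a neutral amino acid transporter, had a ratio of 0.219 (0.211 to 0.226) and Slc5a2, the glucose transporter SGLT2, 0.274. Proximal transport and uptake genes had a median of -0.96 with 19 of 24 lower. Gluconeogenesis and organic acid genes had a median of -1.11 with 15 of 16 lower, and G6pc, the glucose-6-phosphatase of gluconeogenesis, had a ratio of 0.209. All 8 distal convoluted tubule genes were lower, with a median of -1.60, and Pvalb had a ratio of 0.125. Intercalated cell genes had a median of -1.44, with Slc26a4 at 0.136. The vitamin D 24-hydroxylase Cyp24a1 had a ratio of 0.120. Named lower genes also included Cyp4a12a at 0.120, Car3 at 0.136, Cyp2d12 at 0.145, Dnase1 at 0.147, Insrr at 0.150 and Ces1g at 0.169. Renin angiotensin genes had a median of -0.50 (percentile 2.12), where Ren1 had a ratio of 0.210 and Agt was 4.54-fold higher. Fatty acid oxidation and VEGF genes, with medians of -0.24 and -0.14, were not apart from random lists, nor were podocyte genes at -0.06 over whole sections, while region-standardised the podocyte median was 0.30 (percentile 99.1). Mitochondrially encoded genes were lower for 12 of 12 members, with a median of -0.90 that was 0.08 against the mixed library, and immediate early and heat-shock genes higher for 10 of 14, with a median of 1.09.

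Within the 8 regions with enough spots in both libraries, every list that was compared by region kept 1 direction. For example, the injury median lay between 1.84 and 3.13, the macrophage median between 2.24 and 2.83 and the proximal transport median between -1.50 and -0.73. These 8 regions held 3932 of 4093 spots in WT but 1030 of 1997 in 5m AS, since most other 5m AS spots lay in an early-segment-led region of 441 spots and a late-segment-led region of 506 spots that had 0 spots in WT, so within-region and region-standardised values leave these out. Late-segment-led regions held 25.4% (23.5 to 27.4) of spots in 5m AS and 2.44% in WT, and the late proximal tubule list, with a median of 0.12, had -0.40 when region-standardised. A region led by both thick ascending limb and late-segment genes, not counted among them, held 63 spots in 5m AS and 829 in WT. The log2 ratio of Havcr1 was 8.59 over whole sections and 7.86 when region-standardised, that of Serpina10 8.89 and 7.94, and that of Insrr -2.73 and -2.14. With plain CPM 570 genes were higher and 95 lower, and the median of all genes was 0.20 in place of -0.20.

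**Figure D1:**
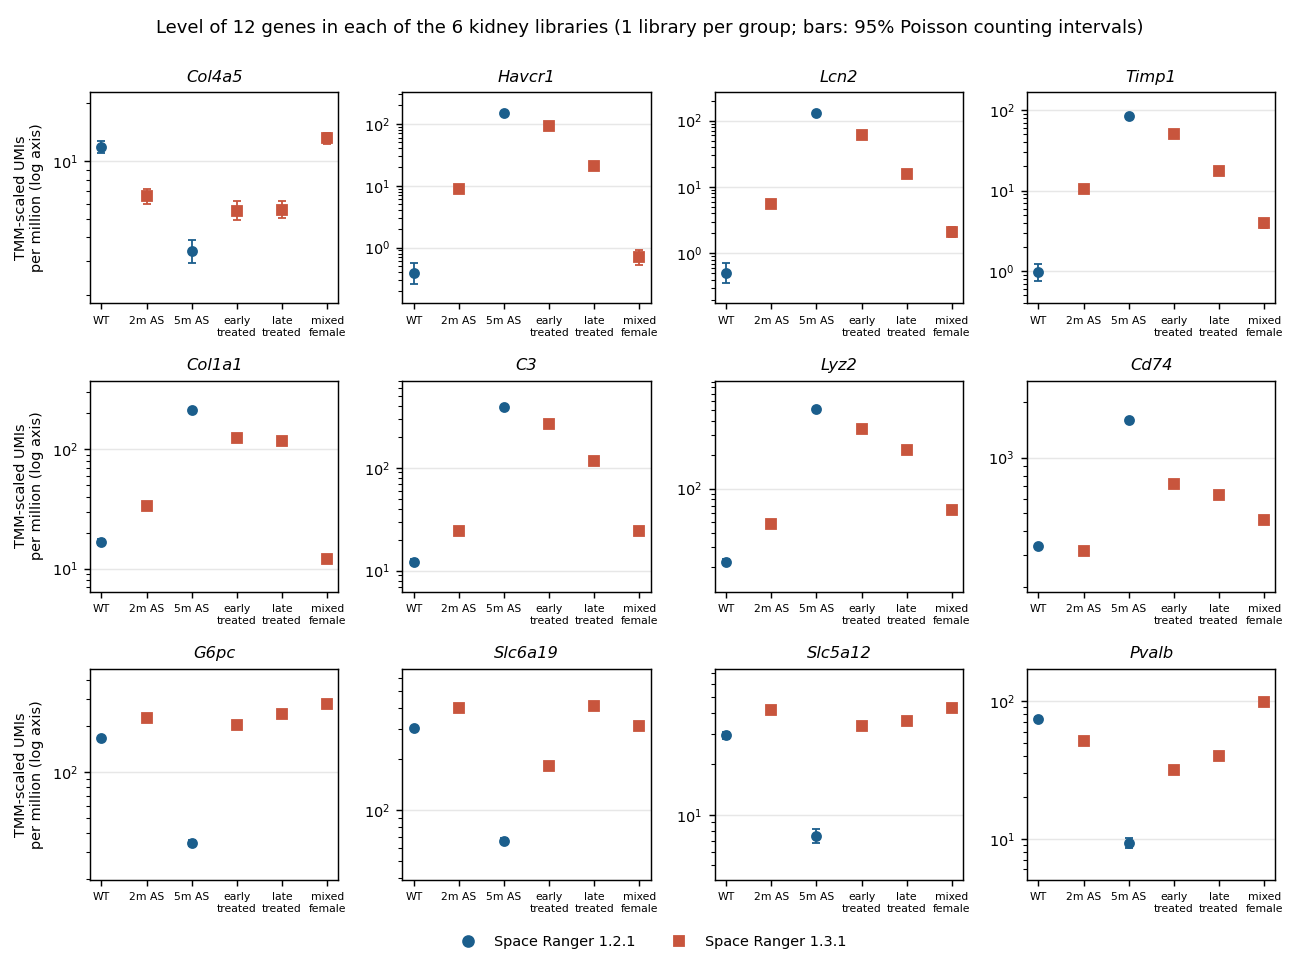
Level of 12 genes in each of the 6 libraries, in scaled CPM on log axes, with circles for Space Ranger 1.2.1 and squares for 1.3.1. Havcr1 runs from 0.395 in WT to 152 in 5m AS, with 94.0 in early treated and 21.1 in late treated 5m AS.

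Between 2 and 5 months of age in Alport kidneys, injury, matrix and immune genes were higher at the later age, and proximal transport and gluconeogenesis genes lower. Lcn2 was 23.3-fold (21.1 to 25.9) and Havcr1 16.9-fold (15.6 to 18.3) higher in 5m AS than in 2m AS. C3 was at 387 against 24.3, 16-fold (15.2 to 16.8). Cyp24a1 was at 5.65 against 156, a ratio of 0.0363 (0.0324 to 0.0404). Of 6806 genes, 396 were at least 2-fold higher and 553 at least 2-fold lower.

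Injury genes were higher for 17 of 18 members, with a median log2 ratio of 2.39, and matrix genes for 21 of 22, with a median of 1.75. All 12 macrophage genes were higher, with a median of 2.38 and Lyz2 at 10.6-fold. Unfolded protein response genes were higher for 11 of 13 members, with a median of 1.05 and Hspa5 at 3.80-fold. Podocyte genes had a median of 0.54 with 6 of 13 higher, and Synpo was 2.97-fold higher. Each of these lists was apart from random lists. Other named higher genes were Serpina10 at 21.2-fold, Aoc1 at 19.5-fold, Hspa1b at 17.8-fold, Ccl2 at 16.2-fold and Hspa1a at 15.4-fold.

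Gluconeogenesis genes were lower for 15 of 16 members, with a median of -1.10 (percentile 0), and G6pc had a ratio of 0.155. Proximal transport genes had a median of -0.84 with 15 of 24 lower, not apart without late-segment-led regions (percentile 3.38), including Slc6a19 at 0.165 and Slc5a12, a lactate transporter, at 0.178. Oxidative phosphorylation genes were lower for 18 of 24 members, but their median of -0.75 was at percentile 21.1 of matched lists. Named lower genes also included Clec2h at 0.0993, Car3 at 0.112, Nat8f3 at 0.139, Slco1a1 at 0.160, Pvalb at 0.183 and the succinate receptor Sucnr1 at 0.194. The libraries came from different Space Ranger versions. With plain CPM 1028 genes were higher and 105 lower, and without mitochondrially encoded genes 1144 and 104.

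The comparisons of treated with untreated 5m AS addressed what differs after hEV. Both used the same 5m AS library, which also stood in the comparison with WT, so an extreme value of that library would appear in all of them. For this reason no overlap or correlation between comparisons is given as a result here, and a direction shared by both is not a repeat. Both treated libraries were made with Space Ranger 1.3.1 and 5m AS with 1.2.1, so treatment and version cannot be told apart.

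The early treated kidney had lower RNA of late proximal tubule, fibroblast, macrophage and heat-shock genes than untreated 5m AS, and higher RNA of early proximal and distal tubule genes. Serpina1f (ENSMUSG00000021081, chromosome 12, 103688044 to 103695529), a serpin, was at 1.37 in early treated and 251 in 5m AS, a ratio of 0.00545 (0.00431 to 0.00680). Cyp24a1 was at 63.4 against 5.65, 11.2-fold (10.0 to 12.6). G6pc was at 203 against 34.6, 5.87-fold (5.60 to 6.16). Of 6591 genes, 69 were at least 2-fold higher and 101 at least 2-fold lower.

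Early proximal tubule genes were higher for 7 of 12 members, with a median log2 ratio of 0.66 (percentile 100) that was 0.34 when region-standardised. Slc5a12 was 4.53-fold, Slc6a19 2.74-fold and Slc5a2 2.51-fold higher. All 8 distal convoluted tubule genes were higher, with a median of 1.23 that was 0.49 when region-standardised, and Pvalb at 3.41-fold. Proximal transport genes had a median of 0.41 with 9 of 24 higher and gluconeogenesis genes 0.53 with 6 of 16 higher. VEGF genes had a median of 0.25 (percentile 99.7) with 3 of 12 higher, 2 lower and Vegfa at 1.69-fold, and were not apart when region-standardised, at 0.12 (percentile 91.0). Named higher genes also included Slpi, a protease inhibitor, at 9.06-fold (7.68 to 10.8), Ces1g at 4.73-fold, Nat8f5 at 4.69-fold, the glycine decarboxylase Gldc at 4.35-fold, Malat1 at 3.68-fold, Lars2 at 3.64-fold and Cyp4a12a at 3.54-fold.

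Late proximal tubule genes were lower for 8 of 10 members, with a median of -1.80 (percentile 0). Beside Serpina1f, the genes named as lower had ratios of 0.00583 for Serpina1d, 0.00857 for Serpina1a, 0.0210 for Bcat1, 0.0303 for Slc22a13, 0.0306 for Cyp7b1, 0.0362 for Slc22a19, 0.0390 for the prolactin receptor Prlr, 0.0396 for Mettl7a2 and 0.0416 for Scd1. Of these named genes, only Serpina1f, Slc22a13 and Cyp7b1 are on the late proximal tubule list. Region-standardised, the list median was -1.08 and the single genes lay closer to 0, with log2 ratios of -5.53 in place of -7.52 for Serpina1f, -3.34 in place of -5.05 for Slc22a13, -2.68 in place of -5.03 for Cyp7b1 and -2.32 in place of -4.66 for Mettl7a2. Macrophage genes were lower for 11 of 12 members, with a median of -0.81 and Csf1r at 0.493. Fibroblast genes had a median of -0.65 with 6 of 10 lower, and matrix genes -0.43 with 9 of 22 lower, including Col6a1 at 0.358. Injury genes had a median of -0.51 with 7 of 18 lower, where Lcn2 had a ratio of 0.472 (0.453 to 0.491) and Havcr1 0.617 (0.596 to 0.638). Complement genes, at -0.15, and NF-kB and chemokine genes, at -0.10, were not apart from random lists over whole sections. Region-standardised, complement genes were, at -0.21 (percentile 0.75), and NF-kB and chemokine genes were not, at -0.07 (percentile 7.90), while without late-segment-led regions both were, at -0.27 (percentile 0.26) and -0.17 (percentile 0.44). The T and NK lymphocyte list, with 3 measured members, had a median of -0.08 and was not apart. Thick ascending limb genes had a median of -0.51, with the salt transporter Slc12a1 at 0.359, and of -0.21 (percentile 2.99) without late-segment-led regions. Immediate early and heat-shock genes were lower for 10 of 14 members, with a median of -1.10 and Hspa1b at 0.121.

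The regions compared held 1471 of 1997 spots in 5m AS for either treated library. Late-segment-led regions held 25.4% of spots in 5m AS and 0.113% (0.0307 to 0.288) in early treated 5m AS, and with region-standardised ratios 86 genes were apart in place of 170. The region led by both thick ascending limb and late-segment genes, not counted among them, held 63 spots in 5m AS and 107 in early treated 5m AS. The podocyte median was 0.49 over whole sections and -0.16 when region-standardised. In early-segment-led regions alone the mural and renin median was -0.14 where it was 0.41, and the intercalated median -0.06 where it was 0.65 (0.31 when region-standardised).

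The late treated kidney had lower RNA of injury, matrix, macrophage, chemokine and unfolded protein response genes than untreated 5m AS, and higher RNA of early proximal and distal tubule genes. Havcr1 was at 21.1 in late treated and 152 in 5m AS, a ratio of 0.139 (0.131 to 0.147). Lcn2 had a ratio of 0.123 (0.115 to 0.131) and Timp1 0.210 (0.197 to 0.224). Cyp24a1 (ENSMUSG00000038567, chromosome 2, 170482708 to 170497145) was at 240 against 5.65, 42.4-fold (38.0 to 47.4). Of 6675 genes, 140 were at least 2-fold higher and 242 at least 2-fold lower.

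Injury genes were lower for 16 of 18 members, with a median log2 ratio of -1.34 (percentile 0), and in each of the 9 regions compared the median lay between -1.62 and -0.86. Matrix genes were lower for 17 of 22 members, with a median of -0.97 and Col3a1 at 0.336. Macrophage genes had a median of -1.09 with 11 of 12 lower, including C1qb, a complement component made by macrophages, at 0.406. NF-kB and chemokine genes had a median of -0.89 with 13 of 17 lower and Ccl2 at 0.223, and complement genes -0.73 with C3 at 0.303. Unfolded protein response genes were lower for 9 of 13 members, with a median of -0.96 and Hspa5 at 0.320. Cell cycle genes had a median of -0.88. The B and plasma cell list had a median of -2.82, with Igkc at 0.141. Late proximal tubule genes were lower for 6 of 10 members, with a median of -1.48 that was -0.80 when region-standardised and -0.53 without late-segment-led regions. The genes named as lower were Serpina1d at 0.00488, Serpina1a at 0.00542, Serpina1f at 0.00551, Bcat1 at 0.0170, Mettl7a2 at 0.0273, Scd1 at 0.0335, Cyp7b1 at 0.0358, Slc22a13 at 0.0418, Prlr at 0.0425 and Hspa1b at 0.0441. Of these, only Serpina1f, Cyp7b1 and Slc22a13 are on the late proximal tubule list. Region-standardised, the log2 ratio of Serpina1f was -6.20 in place of -7.50, that of Cyp7b1 -2.84 in place of -4.80 and that of Mettl7a2 -2.90 in place of -5.20.

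Early proximal tubule genes were higher for 8 of 12 members, with a median of 1.03 (percentile 100), and Slc6a19 was 6.13-fold (5.93 to 6.34) higher. Gluconeogenesis genes had a median of 0.77 with 10 of 16 higher, and G6pc was 6.92-fold higher. Proximal transport genes had a median of 0.60 with 13 of 24 higher. All 8 distal convoluted tubule genes were higher, with a median of 1.3 that was 0.56 when region-standardised, and 7 of 8 intercalated genes, with a median of 1.11 (0.54 when region-standardised) and Slc26a4 at 3.24-fold. Renin angiotensin genes had a median of 0.43 with 3 of 11 higher, including Ren1 at 2.36-fold, and 3 lower, including Agt at 0.210, and were not apart when region-standardised (percentile 95.9). Named higher genes also included Ces1g at 8.44-fold, Clec2h at 8.41-fold, Hmcn2 at 5.27-fold, Slc5a12 at 4.82-fold, Slco1a1 at 4.76-fold, Sectm1b at 4.75-fold and the phosphate transporter Slc34a3 at 4.29-fold. Late-segment-led regions held 0.0692% (0.00838 to 0.250) of spots in late treated 5m AS, and the podocyte median of 0.78 was -0.11 when region-standardised. The region led by both thick ascending limb and late-segment genes, not counted among them, held 122 spots in late treated 5m AS and 63 in 5m AS.

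**Figure D2:**
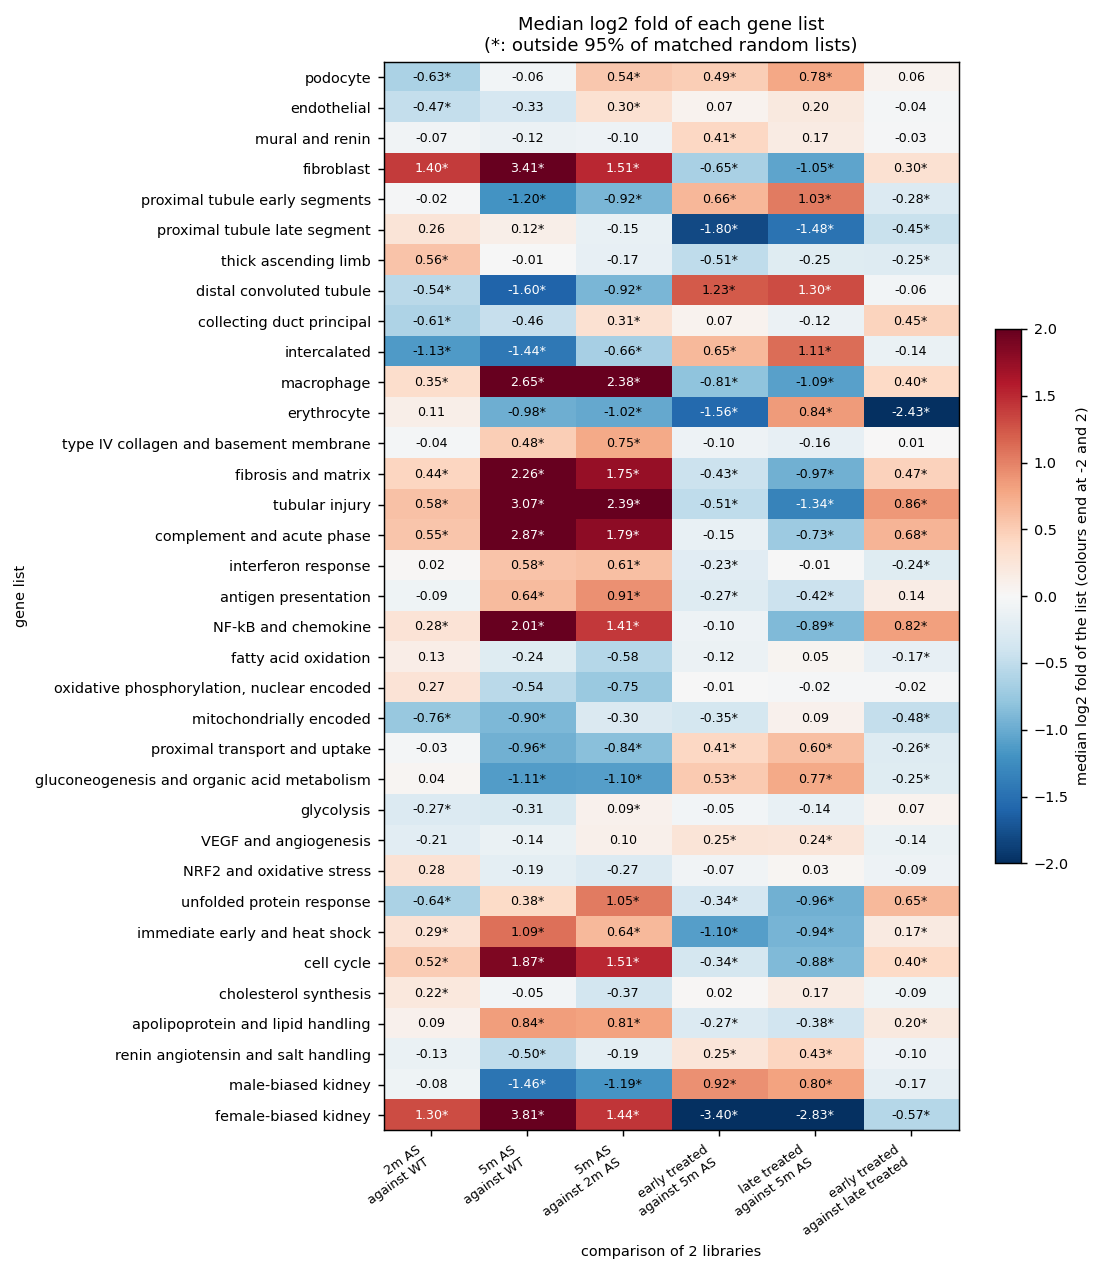
Median log2 ratio of each gene list (vertical axis) in 6 comparisons of 2 libraries (horizontal axis), with an asterisk where the list lies outside 95% of matched random lists. The tubular injury list reads 3.07 for 5m AS against WT, -0.51 for early treated and -1.34 for late treated against 5m AS.

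Early and late treated 5m AS, both made with Space Ranger 1.3.1, differed mainly in injury, chemokine, plasma cell and haemoglobin genes. Havcr1 was 4.45-fold (4.20 to 4.72) and Ccl2 5.36-fold (4.99 to 5.77) higher in early than in late treated. Slpi was at 24.0 against 0.373, 64.4-fold (43.4 to 99.9). Haemoglobin genes were lower in early treated, with Hbb-bs at 118 against 772. Of 6474 genes, 61 were at least 2-fold higher and 21 at least 2-fold lower.

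Injury genes were higher in early treated for 14 of 18 members, with a median log2 ratio of 0.86 (percentile 100), and positive in all 10 regions compared. NF-kB and chemokine genes had a median of 0.82 with 10 of 17 higher, complement genes 0.68 with 9 of 13 higher, unfolded protein response genes 0.65 with 7 of 13 higher and matrix genes 0.47 with 8 of 22 higher. The B and plasma cell list had a median of 2.61, with Jchain, which joins antibody units, at 6.12-fold, and the T and NK list 0.69, with Ccl5 at 2.67-fold. The small heat-shock gene Hspb1 was 4.32-fold higher. Proximal transport genes had a median of -0.26 (percentile 0) with 3 of 24 lower, and Slc6a19 had a ratio of 0.447. Mitochondrially encoded genes had a median of -0.48. The erythrocyte list had a median of -2.43 with 6 of 7 lower. Named lower genes were Cyp24a1 at 0.265, Bcl6 at 0.301, Slc4a1 at 0.306, Clec2h at 0.335 and Aqp6 at 0.415. Distal convoluted tubule genes, at -0.06, and type IV collagen and basement membrane genes, at 0.01, were not apart from random lists.

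**Figure D3:**
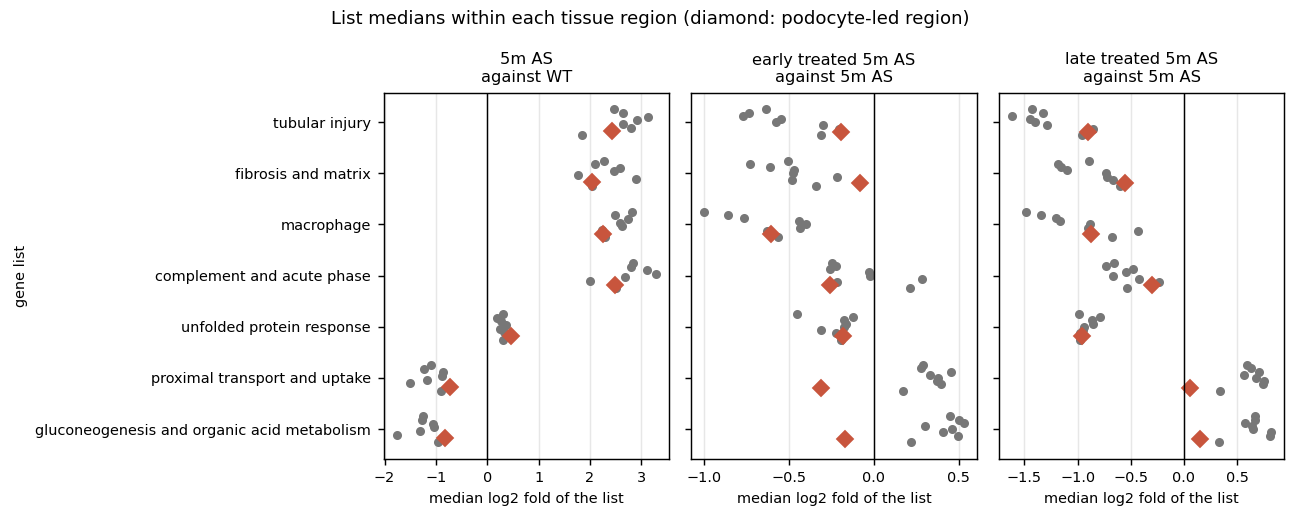
Median log2 ratio (horizontal axis) of 7 gene lists within each region of spots, for 5m AS against WT and each treated library against 5m AS, with a diamond for the podocyte-led region. The injury median is above 0 in 8 of 8 regions for 5m AS against WT and in 0 of 9 for either treated library against 5m AS.

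In the region led by podocyte genes, which held 346 spots in WT, 109 in 5m AS, 256 in early treated and 211 in late treated 5m AS, matrix and complement genes were again high in 5m AS. Col1a1 was at 22.7 in WT, 232 in 5m AS, 137 in early treated and 144 in late treated. C3 was at 37.2, 408, 315 and 181 in the same order, and Timp1 at 2.12, 80.4, 53.6 and 25.6. The matrix list in this region had a median of -0.08 for early treated and -0.55 for late treated against 5m AS. Col4a3, a chain of the glomerular basement membrane, was at 97.7 in WT, 204 in 2m AS, 171 in 5m AS, 372 in early treated and 336 in late treated. The proximal transport median in this region was -0.31 for early treated against 5m AS, so the tubule RNA in these spots differed as well. For late treated against 5m AS it was 0.06, with little difference in this list. The podocyte RNA content of these spots was not compared, so the Col4a3 levels are not corrected for it. Col4a5 was at 15.6 in WT, 18.9 in 2m AS, 8 in 5m AS, 15.5 in early treated and 12.3 in late treated, on 20 to 81 counts. Its ratio of 2m AS to WT here was 1.21 (0.849 to 1.72), while over whole sections it was lower. The injury median in this region was 2.42 for 5m AS against WT, -0.19 for early treated and -0.90 for late treated against 5m AS. Genes that define the region were not compared within it.

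The mixed library of wild-type and heterozygous females was compared with WT as a look at 2 untreated libraries. Female-biased kidney genes were higher for 5 of 6 members, with a median log2 ratio of 5.36, and male-biased genes lower for 9 of 9, with a median of -3.85. Cyp4a14 was 76.7-fold (69.0 to 85.6) higher, Slc7a12 98.7-fold, Hdc, the histamine-forming enzyme, 70.4-fold, Prlr 61.4-fold and Fabp1 40.3-fold. Region-standardised, the log2 ratio of Slc7a12 was 3.80 in place of 6.62 and the female-biased median 4.20. Slc7a13 had a ratio of 0.000849, Cyp2j13 0.00112, Pzp 0.00206 and Acsm3 0.00445. Slco1a1 had 2 counts in the mixed library, a ratio of 7.69e-05 (9.31e-06 to 0.000278). Y-linked genes were lower for 4 of 4 members. Of 6636 genes, 157 were at least 2-fold higher and 231 lower, or 192 and 175 with plain CPM. Macrophage genes had a median of 0.87, injury genes 0.43 and cholesterol synthesis genes 0.55, all apart from random lists. Sex, genotype, the mixing of 2 animals and Space Ranger version all differ between these libraries and cannot be told apart.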

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

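All tests of explanations in this part were chosen after the results were seen, and the 4 heat-shock genes were picked after their values were seen.

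The unfolded protein response list pointed in opposite directions at the 2 ages, with a median log2 ratio of -0.64 for 2m AS against WT and 0.38 for 5m AS against WT. The difference between these effects was not tested, and the direct median of 5m AS against 2m AS was 1.05. The comparison at 2 months crosses Space Ranger versions and the one at 5 months does not, so age and version cannot be told apart here. For this list the mixed library (version 1.3.1) against WT (version 1.2.1) had -0.26 (percentile 5.04, not apart). Early and late treated against 5m AS, which also cross versions, had -0.34 and -0.96. The erythrocyte list pointed in opposite directions in the treated libraries, with -1.56 for early treated and 0.84 for late treated against 5m AS. This difference was not tested either, and early against late treated gave -2.43.

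The 9 genes named as lower in both treated libraries (Bcat1, Cyp7b1, Mettl7a2, Prlr, Scd1, Serpina1a, Serpina1d, Serpina1f and Slc22a13) were chosen after their values were seen, from 2 comparisons that share the 5m AS library, so a high level in that library alone would give the same pattern. The share of late-segment-led regions stays open: without these regions the median log2 ratio of the 9 genes was -3.26 in early treated and -3.42 in late treated, but most of the 9 also lead the regions left out, and the late proximal tubule list fixed beforehand went from -1.80 to -1.05 and from -1.48 to -0.53. RNA of late-segment cells in the remaining spots of 5m AS stays open too, with levels in early-segment-led over late-segment-led regions that ranged 2.28-fold across the 9 genes. Space Ranger version cannot be excluded: the 9 genes had a median of 2.78 in 2m AS (version 1.3.1) against WT (version 1.2.1), with all 9 higher, and of 1.99 in the mixed library (version 1.3.1) against WT, with 7 of 9 higher. Both medians are opposite to the pattern, but age, genotype or sex differs in these comparisons as well. An effect of hEV cannot be told apart from a difference in where the kidneys were sectioned or between animals, with 1 untreated 5m AS library.

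Hspa1a, Hspa1b, Dnajb1 and Hsph1 were low in the 4 libraries of the later Space Ranger version. Hspa1a was at 108 in WT and 184 in 5m AS, and between 10.9 and 27.2 in the other 4. The median log2 ratio to WT was -2.34 in 2m AS and -1.38 in the mixed library, both untreated, so low levels of these genes were also found without hEV. The genes were picked for being low in all 4 libraries, so these values restate that choice and are not a test of hEV. In the 2 treated libraries alone an effect of hEV stays open, since their medians against 5m AS of -1.98 (early) and -2.96 (late) also cross Space Ranger versions. The immediate early and heat-shock list, which holds 3 of these genes but not Hsph1, had medians of 0.29 in 2m AS and 0.48 in the mixed library against WT. A processing or handling batch that follows the version stays open: 7 genes split the libraries 1.5-fold by version, while the 14 other splits into 2 and 4 libraries gave between 0 and 169. Hspa1a, Hspa1b, Dnajb1 and Hsph1 are among these 7 genes and were picked for this pattern, so they add no support of their own. Hspa1a and Hspa1b are close paralogs, so their counts are not independent.

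The tubular injury list fixed beforehand was lower in both treated libraries than in 5m AS, and both comparisons use that 1 library. The share of regions in the sections is argued against as the whole cause, since the region-standardised median was -0.52 in early treated and -1.29 in late treated, over regions that held 1471 of 1997 spots in 5m AS. Space Ranger version cannot be excluded: the mixed library (version 1.3.1) had a median of 0.43 against WT (version 1.2.1), but these libraries also differ in sex and genotype. A difference between animals stays open too, since the 2 treated libraries were 0.86 apart from each other. With 1 animal per group, an effect of hEV is 1 of several explanations that remain untested.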

How the results depend on the processing

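Of the alternatives, leaving out the late-segment-led regions was chosen after seeing the data. For the 120 results on named genes, 1200 alternative values gave 0 reversals of direction, with 724 inside the counting interval and 476 outside it. Of the 10 settings, plain CPM and equal weight for each spot were part of the naming rule and could not reverse a named gene. The named genes were also chosen for large ratios, so settings that change only scaling or depth had little room to reverse them. The mixed library was not used as reference for named genes, and levels there were opposite for some: Cyp4a14 was at 62.7 in 2m AS and 386 in the mixed library, and Slco1a1 at 39.0 in 5m AS and 0.0287 in the mixed library. For the 159 list medians that were apart, 140 kept their sign in each alternative run, and of 1634 alternative values 28 had the opposite sign, 763 kept the sign but left the spread of resampled counts and 843 lay within it. Requiring 50 scaled CPM left fewer genes to count and gave 97 for 2m AS against WT, 368 for 5m AS against WT, 611 for 5m AS against 2m AS, 108 for early treated against 5m AS, 244 for late treated against 5m AS, 46 for early against late treated and 257 for the mixed library against WT. With no minimum, more genes were counted, many on few UMIs: 2032, 4097, 4855, 1713, 2661, 1384 and 2493 in the same order. For the values that follow, the cause was not tested. In early-segment-led regions alone, where 441 of 626 spots of 5m AS lay in a region with 0 spots in WT, 389 genes were apart for 5m AS against WT and 97 for early treated against 5m AS, where region-standardised ratios gave 86 at either resolution and leaving out late-segment-led regions gave 100. With the mixed library as reference, 307 genes were apart in 2m AS.

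Against the mixed library, medians of 2m AS turned to -0.55 for thick ascending limb, -0.59 for macrophage, -0.37 for NF-kB and chemokine, 0.32 for mitochondrially encoded, -0.13 for immediate early and heat shock, -0.27 for cholesterol synthesis and -2.12 for female-biased genes. Medians of 5m AS turned to 0.08 for mitochondrially encoded, 3.39 for male-biased and -1.91 for female-biased genes, and the mixed library is of females. The late proximal tubule median of 5m AS against WT turned to -0.12 with equal weight for each spot, -0.15 in early-segment-led regions, -0.40 and -0.39 when region-standardised with finer and coarser regions, and -0.45 without late-segment-led regions. In early-segment-led regions the intercalated median of 5m AS against 2m AS was 0.13, and early treated against 5m AS gave -0.33 for podocyte, -0.14 for mural and renin, -0.06 for intercalated and -0.23 for renin angiotensin genes. Region-standardised with finer and coarser regions, early treated gave -0.16 and -0.17 for podocyte and 0.014 and 0.019 for apolipoprotein genes. Late treated gave -0.23 for podocyte in early-segment-led regions and -0.11 and -0.16 when region-standardised. The interferon median of early against late treated was 0.029 with equal weight for each spot. Depth limits low genes: the floor of 3 counts corresponds to 0.0521 scaled CPM in the shallowest library, and 1 library per group leaves the spread between animals unknown.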

Other observations

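Genes that differ between the sexes in mouse kidney also differed between libraries that all expressed Y-linked genes. Male-biased genes had a median log2 ratio of -1.46 in 5m AS against WT, with 6 of 9 lower (-1.41 when region-standardised), and were higher in early treated (0.92) and late treated (0.80) than in 5m AS, with 5 of 9 higher and 2 lower in each, or 0.58 and 0.47 when region-standardised. Early proximal tubule genes went the same way, with medians of -1.20, 0.66 and 1.03 in the same comparisons. Whether the difference is particular to male-biased genes was not tested. Female-biased genes had a median of 3.81 in 5m AS against WT and of -3.40 in early treated and -2.83 in late treated against 5m AS, which were 1.65, -2.44 and -1.99 when region-standardised. Against the mixed library, the 5m AS medians were 3.39 for male-biased and -1.91 for female-biased genes. Cyp4a14 was at 5.03 in WT, 62.7 in 2m AS, 170 in 5m AS, 16.1 in early treated, 23.9 in late treated and 386 in the mixed library. Cyp7b1, on the male-biased list, and Prlr, on the female-biased list, are also among the genes named as lower in both treated libraries.

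A region led by a mix of interferon-induced (Cxcl10, Iigp1, Igtp), chemokine (Ccl5, Ccl2), macrophage (Lyz2), complement (C3), antigen presentation (Cd74) and tubular injury (Vcam1, Havcr1) genes held 0.635% (0.415 to 0.929) of spots in WT, 2.37% (1.87 to 2.95) in 2m AS and 19.3% (17.6 to 21.1) in 5m AS. It held 17.0% (15.8 to 18.3) in early treated, 11.9% (10.7 to 13.1) in late treated and 1.88% (1.45 to 2.40) in the mixed library. Oxidative stress genes of the NRF2 list had medians of -0.07 in early treated and 0.03 in late treated against 5m AS, not apart from random lists.

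For 4 of the 42 lists fewer than 3 members were measured in each comparison. Their highest levels were Sprr1a at 17.5 in 5m AS for papilla and urothelium, S100a9 at 10.8 in the mixed library for neutrophils, Car3 at 57.0 in 2m AS for adipocytes and Xist at 22.1 in the mixed library for X-inactivation.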
